A study of Homo sapiens with 9 samples.

How the data were processed

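Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7, aligned to GRCh38 with HISAT2 2.2.1 and summarised per gene with StringTie 2.1.7; the annotation release is not given in the sources used here. Per the file headers, the deposited coverage value was StringTie's mean per-base read depth of each gene. The deposited FPKM value was, per the file headers, that abundance normalised by the authors for gene length and sequencing depth. The deposited TPM value was, per the file headers, the same abundance rescaled by StringTie so that each library has the same total. Per the labels, libraries were made from total RNA with a directional kit. Read counts were not analysed here, and alignments were not used here.

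The 9 libraries held 60660 gene IDs each. A gene ID given more than once in a library had its TPM and FPKM values summed and its coverage values averaged. Values were used as log2 of TPM plus 1, over the 14997 gene IDs with a mean of at least 1 TPM over the 9 libraries. Gene types came from GENCODE 29, matched for 58429 gene IDs. Depth was estimated from single-exon genes longer than 300 bases whose coverage was that of 1 read of 76 bases, 96 to 150 genes per library, so it rests on an assumed read length. Median-of-ratios factors over 13383 genes ranged from 0.9056 to 1.0658.

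Limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with 7 coefficients, namely the line, doxycycline within each line and 48 h against 24 h shared by the lines, which left 2 residual degrees of freedom. Empirical Bayes moderation used a trend, with 6.015 prior degrees of freedom, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were the doxycycline change of shRCOR2 minus that of shCTRL, of shRCOR1 minus shCTRL, of shRCOR2 minus shRCOR1, and of shCTRL alone. Untreated libraries, listed at 48 h, were coded without the 48 h term, so the change of shCTRL alone was estimated at the 24 h level. In the contrasts between lines this term cancels. Genes were said to have risen or fallen where they passed this test. The size rule took genes whose change against the own untreated library was at least 1 log2 unit with the same sign at 24 h and 48 h, and untreated lines were compared by a difference of at least 1 log2 unit.

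Named genes had a symbol, clone-style names such as those starting with AC or AL and a number not counting as symbols, and at least 10 TPM in at least 1 of the compared libraries. They were ranked by the smallest absolute value among the changes at 24 h and 48 h against the own untreated library and the same changes minus those of shCTRL, all of the same sign, and the first 12 higher and 12 lower per targeted line were named. For shCTRL the 24 h and 48 h changes were used and the first 6 and 6 named. RCOR1, RCOR2, RCOR3, KDM1A and list members were named as well. A gene named by this rule as higher in shRCOR1 and a member of the adrenergic list are not reported here.

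There were 23 gene lists: adrenergic transcription factors, the noradrenergic phenotype, mesenchymal neuroblastoma markers, the CoREST complex and partners, REST-bound neuronal genes, the neurite and neuronal cytoskeleton, the Notch pathway, DNA replication, mitosis, MYCN-linked ribosome biogenesis, p53 targets, the integrated stress response, ER chaperones, sterol biosynthesis, glycolysis and hypoxia, the interferon response, immediate early genes, mitochondrially encoded mRNAs, apoptosis regulators, Schwann and glial markers, fibroblast, endothelial and blood markers, replication-dependent histones, and small RNA and nuclear transcripts. They were written from general knowledge of these pathways. The median of each list was placed among 10000 random lists of the same size matched in 20 bins of expression, and a list was taken as apart when its percentile lay outside the central 95% of them. The p-values of list members were also adjusted over the list alone.

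The size rule, the limma model, the naming rule, the gene lists and the alternatives in pseudocount, filter, scaling, threshold, time and model were set before the data were examined. Chosen after seeing the data were TPM rescaled without the small structured RNAs 7SL, 7SK, RPPH1 and RMRP, untreated shCTRL replaced by the mean of the other untreated libraries, the shCTRL change not subtracted, the same settings for the untreated lines, the lists of NRF2 and SRF targets, and the scan of 3′ UTR words. The scan compared the change of genes with and without each 7-base word in GENCODE 29 3′ UTRs of at least 50 bases, over 9803 of 10969 genes with a mean of at least 5 TPM and 15628 words held by at least 100 genes. Words found in a random part of the genes were also compared, in the other genes, with 10000 random sets matched in 20 bins of 3′ UTR length and 3 of GC.

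The size rule was tested on simulated data and found 200 of 200 planted genes with 0 others called. The planted change of 1.5 log2 units lay above the threshold, so the test checked only that the rule was computed as stated. It gives no rate of false calls for real libraries, where the rule called 82 genes in shCTRL. The limma fit was tested on simulated data with 5 simulations per setting. With each gene's spread drawn from the fitted prior it recovered 1.6% of genes planted at 1 log2 unit and 63% of those at 2 log2 units. Of its calls 5.8% were false. With each gene's fitted spread it recovered 26.8% and 93.8%, and 13.5% of its calls were false. The simulated libraries shared each gene's mean and took their noise from the spread of this fit. These percentages therefore hold no spread between cultures or lines and give no rate of false calls for the real contrasts. The word scan was tested on simulated data as well: 10 of 10 planted words came first, and the lowest z over 20 shuffles was -4.45. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.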

Results

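RNA abundance was measured in Kelly cells, an established human neuroblastoma line with MYCN amplification and an adrenergic, sympathetic-neuron-like identity. The cells carried a doxycycline-inducible shRNA against RCOR1, an shRNA against RCOR2, or a non-targeting shRNA named shCTRL. RCOR1 and RCOR2 encode corepressor proteins that join the histone demethylase LSD1, the product of KDM1A, to the histone deacetylases HDAC1 and HDAC2. Per the series design, the question was what each of the corepressors does in transcription. Each of the 3 lines gave 1 untreated library, 1 library after 24 h and 1 after 48 h of doxycycline at 2 µg/mL, which makes 9 libraries, 1 per group. The untreated libraries are listed at 48 h, so changes at 24 h also differ in time. The estimated depth was 55.7, 35.8 and 45.7 M reads in shCTRL, 46.8, 26.0 and 45.4 M in shRCOR1 and 63.0, 29.5 and 48.7 M in shRCOR2, in the order untreated, 24 h and 48 h. Between 14859 and 15049 genes reached 1 TPM in a library. Values below are TPM, in that same order of libraries unless stated otherwise. No group had replicates, so no difference between libraries had a replicate check. The p-values came from limma, which took the 24 h and 48 h libraries of a line as repeated observations of treated cells and assumed that each lone untreated library varied like the others. Each untreated library was fitted exactly, so the residual spread came only from how the lines differed in their 24 h to 48 h step. The p-values therefore hold no spread between cultures, and separate cultures are not stated in the labels.

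The targeted genes were lower in the lines carrying their shRNAs. RCOR2 (ENSG00000167771.6, chromosome 11, 63911230 to 63917164) fell in shRCOR2, from 61.3 TPM to 12.7 and 11.2, a limma log2 change over shCTRL of -1.89 (SE 0.26, adjusted p = 0.043). RCOR2 measured 61.0, 42.5 and 51.2 TPM in shCTRL and 52.1, 32.5 and 32.2 TPM in shRCOR1. RCOR1 (ENSG00000089902.10, chromosome 14, 102592649 to 102730561) measured 6.21, 3.37 and 3.01 TPM in shRCOR1, with a log2 change over shCTRL of -0.95 (SE 0.27) that did not pass limma (adjusted p = 0.32). RCOR1 measured 8.67, 10.5 and 9.19 TPM in shCTRL and 9.73, 9.72 and 7.27 TPM in shRCOR2. The third family member, RCOR3, measured 27.5, 33.1 and 21.2 TPM in shRCOR2 and 25.8, 24.5 and 29.7 TPM in shRCOR1. KDM1A measured 355, 281 and 267 TPM in shRCOR2 and 306, 229 and 260 TPM in shRCOR1, against 308, 279 and 305 TPM in shCTRL. The mean log2 change against the own untreated library was -0.78 for RCOR1 in shRCOR1 and -2.27 for RCOR2 in shRCOR2.

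**Figure D1:**
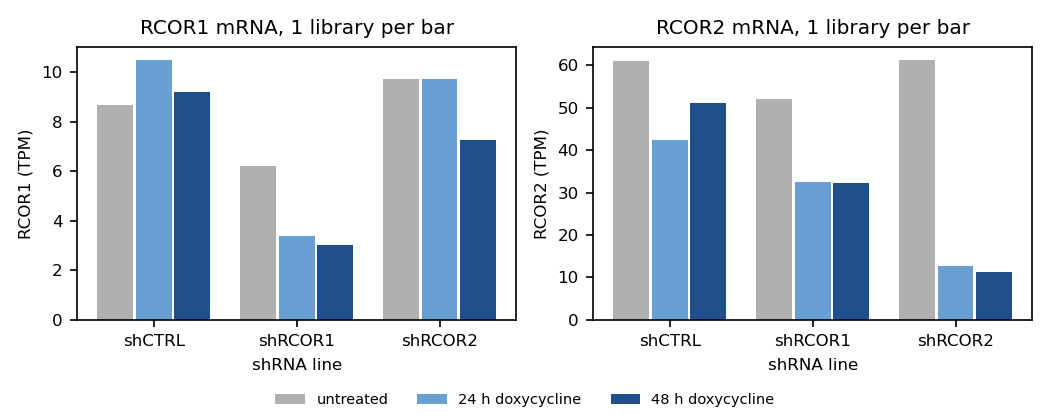
TPM of RCOR1 (left) and RCOR2 (right) in the 3 shRNA lines, 1 library per bar, untreated in grey and after 24 h and 48 h of doxycycline in light and dark blue. RCOR1 stood at 3.01 TPM in shRCOR1 and RCOR2 at 11.2 TPM in shRCOR2 after 48 h.

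The shCTRL line gave the background of doxycycline and a non-targeting shRNA. Mitochondrially encoded mRNAs were higher after doxycycline, from a low start, since their median was 588 TPM in untreated shCTRL against 1050 and 1040 TPM in untreated shRCOR1 and shRCOR2. MT-ND3, a subunit of respiratory complex I, rose from 62.9 TPM to 393 and 249, where the other untreated libraries measured 196 and 219 TPM. Its log2 changes were 2.62 at 24 h and 1.97 at 48 h, and limma gave 2.70 at the 24 h level (SE 0.17, adjusted p = 0.00051). MT-ND6, another complex I subunit, rose from 18.1 TPM to 106 and 60.3. The mitochondrial transfer RNA MT-TS1, the mitochondrial pseudogene MTND1P23 and the ribosomal protein pseudogenes RPS15AP38 and RPS15AP12 also rose, the pseudogenes being uncertain because they share reads with near-identical copies. The ribosomal RNA copies RNA5-8SN2, RNA5-8SN3 and 5_8S_rRNA, the ribosomal spacer microRNA loci MIR3648-1 and MIR3648-2 and a gene ID sharing the symbol RMRP fell. The ribosomal RNA and MIR3648 genes were high in the untreated shCTRL library itself, with MIR3648-1 at 166 TPM there against 1.90 and 1.75 TPM in untreated shRCOR1 and shRCOR2. The gene ID sharing the symbol RMRP measured 129, 8.02 and 2.42 TPM in shCTRL and 95.6, 5.67 and 2.85 TPM in shRCOR1. The list of integrated stress response genes, targets of the ATF4 program, had a median change of 0.61 log2 (percentile 100 of matched random lists), with ASNS at 58.1, 118 and 123 TPM and CHAC1 at 10.4, 32.2 and 28.8 TPM. Sterol biosynthesis genes had a median of 0.26 log2 (percentile 100) and Notch pathway genes a median of -0.34 log2 (percentile 0), with DLL3, a Notch ligand, at 56.2, 34.7 and 41.6 TPM.

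By the size rule, a change of at least 1 log2 unit with the same sign at both times, 52 genes were higher and 30 lower in shCTRL, and limma called 41 genes, 26 higher and 15 lower. Under median-of-ratios scaling limma called 23 of them. With untreated shCTRL replaced by the mean of the other untreated libraries it called 15, of which 6 were among the 41. Without the 24 h or the 48 h library limma called more genes, but each fit had 1 residual degree of freedom. Its prior degrees of freedom were infinite, so each gene's spread came from the trend alone.

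The named genes that fell in shRCOR2 were single genes of varied function, and no pathway shared by all of them was tested. TXNRD1, the cytosolic thioredoxin reductase (chromosome 12, 104215779 to 104350307), fell from 215 TPM to 41.9 and 30.3 (limma log2 over shCTRL -2.60, SE 0.31, adjusted p = 0.031), and SRXN1, which repairs oxidised peroxiredoxins, fell from 33.0 TPM to 7.31 and 5.81. ACTB, the cytoplasmic beta-actin gene (chromosome 7, 5526409 to 5563902), fell from 3540 TPM to 810 and 679 (limma log2 -2.30, SE 0.26, adjusted p = 0.031), while it measured 3290, 3120 and 3690 TPM in shCTRL. DNMT3B, a de novo DNA methyltransferase, fell from 13.9 TPM to 2.67 and 2.54, and CNOT11, a subunit of the CCR4-NOT deadenylase, fell from 22.9 TPM to 6.48 and 5.56. C4orf3, IGBP1 and SMN2 fell as well, SMN2 being uncertain because it shares reads with its near-identical copy SMN1. STMN1, which destabilises microtubules, measured 606, 162 and 78.0 TPM without passing limma (adjusted p = 0.098), and FRRS1, TAF15 and MRPL42 also did not pass.

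None of the 12 genes named by the same rule as higher in shRCOR2 passed limma, with adjusted p between 0.087 and 0.45. SCRT1, a neuronal zinc-finger repressor of the Snail family, measured 12.2, 26.9 and 29.1 TPM, and ETV1, an ETS transcription factor, 10.1, 23.1 and 20.2 TPM. NTPCR measured 19.3, 39.8 and 50 TPM, and NR1H2, which encodes the oxysterol receptor LXR-beta, 15.5, 26.2 and 29.8 TPM. FOS, an immediate early gene, measured 5.33, 27.5 and 9.83 TPM. The others were DDT, NTAN1, C2orf81, THAP8, CC2D1B and the mitochondrial RNAs MT-TC and MT-RNR2. The 3′ UTRs of 10 of the 12 lower genes held the 6-base word ATGGCT, against 35.3% of the 9803 genes searched, a search made after the lower genes had been seen. That word came from a scan of these same shRCOR2 changes, so the share is no independent support. Random sets matched on 3′ UTR length and GC to the genes lower by the size rule held it at 45.1% on average.

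By the size rule 25 genes were higher and 191 lower in shRCOR2, and 84.8% of the lower genes were protein-coding. The median change of all genes in this line was -0.10 log2 at 24 h and -0.20 log2 at 48 h, and 0.003 and 0.005 log2 after median-of-ratios scaling, so list medians are given beside those of matched random lists. At 48 h, 163 genes were at least 2-fold higher and 821 lower, a split that scaling changed to 318 and 443; for the size rule, scaling gave 34 higher and 134 lower. Over shCTRL, limma called 33 genes, 10 higher and 23 lower, of 2118 genes at an unadjusted p under 0.05. Under median-of-ratios scaling 2 of the 33 remained, the 8 named genes that fell having adjusted p between 0.082 and 0.14 with changes of similar size, -2.38 log2 for TXNRD1 and -2.07 for ACTB. With untreated shCTRL replaced by the mean of the other untreated libraries, limma called 328 genes, 23 of them shared. In that fit part of the untreated shRCOR2 level cancels and differences between the untreated lines enter. The larger count is therefore no support for the calls. Fits without 1 doxycycline library of shRCOR2 or shCTRL called more genes than the main fit. They had 1 residual degree of freedom, so the larger counts are no support for the calls.

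**Figure D2:**
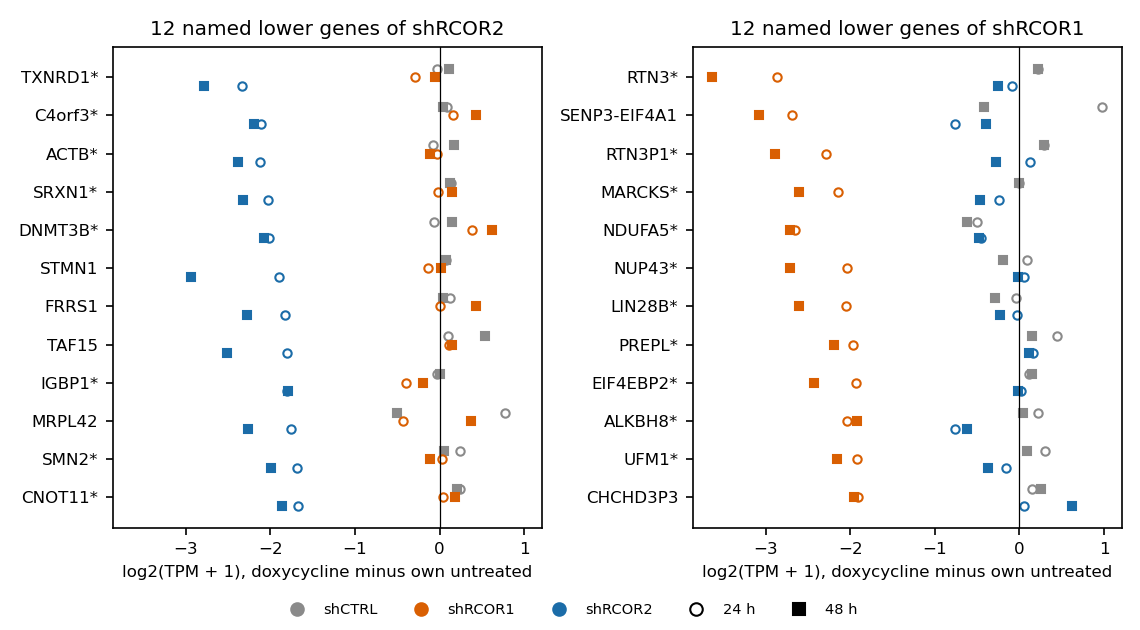
Change in log2(TPM + 1) against the own untreated library of the 12 genes named as lower in shRCOR2 (left) and in shRCOR1 (right), with shCTRL in grey, shRCOR1 in orange and shRCOR2 in blue, open circles for 24 h and filled squares for 48 h, 1 library pair per symbol. An asterisk marks genes that passed limma over shCTRL, 8 of 12 on the left and 10 of 12 on the right.

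Sterol biosynthesis genes, which encode the mevalonate and cholesterol pathway and its regulators, were the list lowest against its matched lists in shRCOR2 together with the glycolysis and mitochondrial lists. Of 21 measured sterol genes 20 were lower in all 4 comparisons, at each time against the own untreated library and relative to shCTRL, and the median over shCTRL was -0.81 log2 against -0.26 in matched lists (percentile 0). Part of this was the higher level in shCTRL, since the median against the own untreated library was -0.51 log2 (percentile 0.03). HMGCS1 measured 86.2, 62.0 and 46.2 TPM and MSMO1 68.1, 43.5 and 28.5 TPM; both passed limma when adjusted over the list alone. No member passed over all genes, with 12 at an unadjusted p under 0.05. Glycolysis and hypoxia genes had a median of -0.77 log2 against -0.22 (percentile 0), with 18 of 19 lower in all 4 comparisons. LDHA, which makes lactate, measured 727, 272 and 150 TPM, the glucose transporter SLC2A1 496, 216 and 135 TPM and the hexokinase HK2 90.9, 35.1 and 34.2 TPM. These 3 and PFKFB4, PDK1 and KDM3A passed when adjusted over the list alone, 6 genes in all; none passed over all genes and 11 had an unadjusted p under 0.05.

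Mitosis genes had a median of -0.61 log2 over shCTRL against -0.27 in matched lists (percentile 0.03, from 2.71 at 24 h and 0 at 48 h), with 21 of 24 lower in all 4 comparisons. BIRC5, which encodes survivin of the chromosomal passenger complex, measured 186, 59.6 and 39.9 TPM and was the 1 gene that passed adjusted over the list alone; none passed over all genes and 5 had an unadjusted p under 0.05. DNA replication genes had a median of -0.36 log2 (percentile 12.36), with 20 of 25 lower in all 4 comparisons. MCM4, a subunit of the replicative helicase, measured 137, 50.8 and 31.8 TPM and was the 1 gene passing adjusted over the list alone. In shCTRL itself the replication list had a median of -0.13 log2 (percentile 0.03). Against the own untreated library it lay at percentile 0.05 in both shRCOR2 and shRCOR1. No replication gene passed over all genes in shRCOR2, where 9 had an unadjusted p under 0.05.

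Immediate early genes, which respond within minutes to growth factors and to serum, had a median of 0.60 log2 over shCTRL against -0.16 in matched lists (percentile 100) in shRCOR2, with 11 of 14 higher in all 4 comparisons. EGR1 measured 1.74, 6.73 and 6.50 TPM and IER2 23.1, 23.6 and 33.1 TPM, and these 2 passed adjusted over the list alone; none passed over all genes and 4 had an unadjusted p under 0.05. The p53 target list had a median of 0.05 log2 against -0.23 (percentile 99.49, from 73.91 at 24 h and 100 at 48 h), with CDKN1A, the cell cycle inhibitor p21, at 21, 18 and 51.4 TPM. The 1 gene passing adjusted over the list alone was SESN1, which was lower, at 8.47, 3.63 and 2.60 TPM. Integrated stress response genes had a median of 0.00 log2 over shCTRL against -0.24 (percentile 99.29, from 39.3 at 24 h and 100 at 48 h) and of 0.65 log2 against the own untreated library, where shCTRL stood at 0.61. SLC7A5, a large neutral amino acid transporter in this list, went the other way and fell from 134 TPM to 58.7 and 45.1 (limma log2 -1.82, SE 0.25, adjusted p = 0.043), and with the serine synthesis gene PSAT1, at 81.8, 60.1 and 49.3 TPM, it was among the 2 that passed adjusted over the list alone.

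Apoptosis regulators had a median of -0.48 log2 in shRCOR2 against -0.22 (percentile 1.30), with BCL2, MCL1, BAK1 and HRK, 4 genes, passing adjusted over the list alone; MCL1, an antiapoptotic member, measured 109, 65.8 and 48.0 TPM. Mesenchymal neuroblastoma markers had a median of -0.48 log2 against -0.20 (percentile 0.63), with FOSL2 at 19, 12 and 8.35 TPM and TEAD1 at 51.3, 29.5 and 17.1 TPM passing adjusted over the list alone, 2 genes of 20 measured. Both lists came inside the range of matched lists under some settings, at percentiles of up to 8.39 and 8.29, as did the p53 target list at 93.55. At 24 h alone the percentiles were 3.96 for apoptosis and 9.88 for mesenchymal markers. Genes of the adrenergic transcription factor circuit had a median of -0.34 log2 (percentile 14.28) and none of 24 passed, with MYCN at 1180, 994 and 875 TPM. The noradrenergic phenotype list had a median of -0.19 log2 (percentile 67.44); its vesicular monoamine transporter SLC18A2 measured 107, 34.4 and 14.8 TPM (limma adjusted p = 0.17) and was the 1 gene passing adjusted over the list alone.

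Of 18 measured CoREST complex members and partners, RCOR2 was the 1 that fell in shRCOR2 over all genes and adjusted over the list alone, and 17 did not pass (list median -0.23 log2, percentile 54.69). HDAC2 measured 111, 66.0 and 36.8 TPM and REST, the neuronal gene repressor that recruits the complex, 8.69, 6.95 and 3.07 TPM. REST-bound neuronal genes had a median of -0.09 log2 over shCTRL (percentile 93.57) and 0 of 30 passed by limma over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05. Against the own untreated library that list lay at percentile 100 in shRCOR2, 99.45 in shRCOR1 and 99.96 in shCTRL. Limma also passed 0 genes, over all genes or adjusted over the list alone, for neurite and neuronal cytoskeleton genes (22 measured, median -0.27 log2, percentile 36.77, 3 at an unadjusted p under 0.05), the Notch pathway (9 measured, -0.20 log2, percentile 53.66, 0 unadjusted), MYCN-linked ribosome biogenesis (24 measured, -0.22 log2, percentile 64.45, 5 unadjusted), ER chaperones (18 measured, -0.41 log2, percentile 5.28, 1 higher and 7 lower unadjusted) and the interferon response (9 measured, 0.06 log2, percentile 84.11, 0 unadjusted).

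Measures of library makeup moved with these groups in shRCOR2. The protein-coding share of TPM was 66.86% untreated, 59.48% at 24 h and 56.55% at 48 h in shRCOR2, against 60.71% to 64.11% in the other 6 libraries, and the share of 7SL, the RNA of the signal recognition particle, was 20.62%, 26.96% and 30.22%. The list of small RNA and nuclear transcripts had a median of 0.28 log2 over shCTRL (percentile 100, down to 93.55 under other settings) with 2 genes at an unadjusted p under 0.05, and replication-dependent histones a median of -0.05 log2 (percentile 93.11) with 0 unadjusted; limma passed 0 genes of either, over all genes or adjusted over the list alone. Schwann and glial markers (4 of 11 measured) had a median of -0.61 log2 (percentile 3.59, and 1.29 to 99.19 under other settings), and fibroblast, endothelial and blood markers (6 of 15 measured) a median of -0.04 log2 (percentile 80.85), with 0 passing limma and 0 unadjusted in both. Mitochondrially encoded mRNAs had a median of -0.83 log2 over shCTRL (percentile 0) although they were 0.48 log2 above the own untreated library. MT-ND3 passed limma with a smaller doxycycline change than in shCTRL (log2 -1.81, SE 0.22, adjusted p = 0.035). It measured 219, 428 and 219 TPM in shRCOR2 against 62.9, 393 and 249 TPM in shCTRL. Its level was thus higher in shRCOR2 untreated and at 24 h, and the contrast rested on the low untreated shCTRL library. Of the 13 mitochondrial mRNAs, 9 passed adjusted over the list alone. The mitochondrial share was 1.02% in untreated shCTRL and 1.66% to 3.13% in the other libraries.

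**Figure D3:**
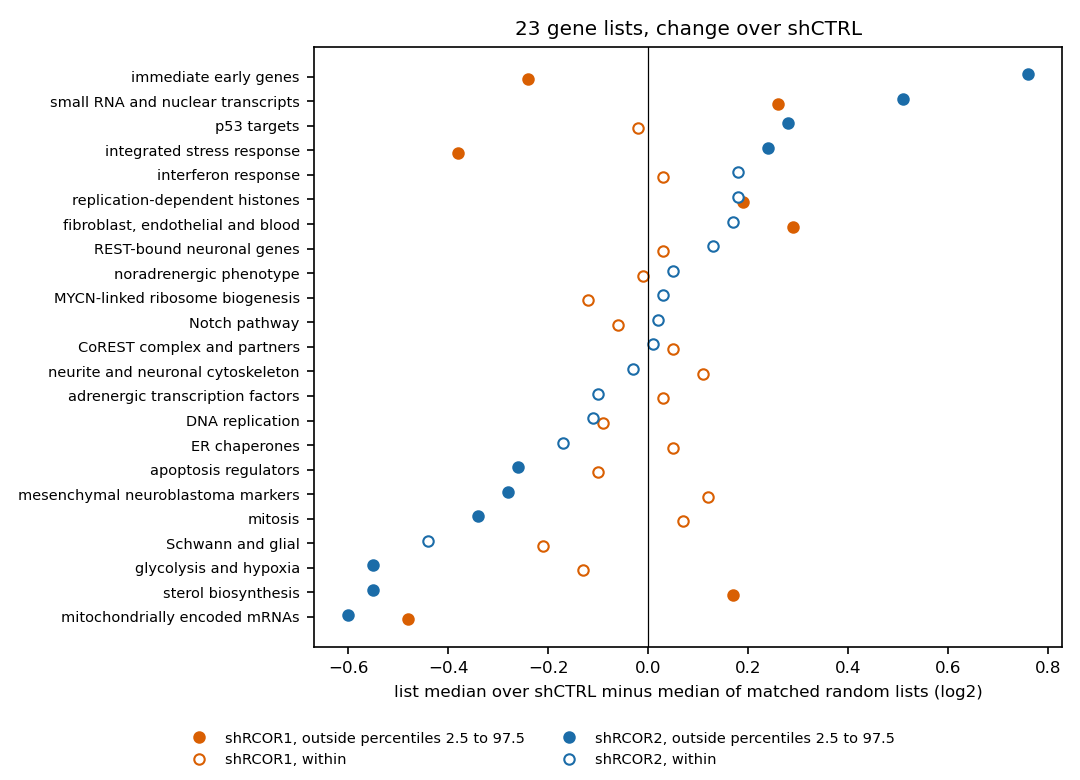
Median log2 change over shCTRL of each of 23 gene lists minus the median of its matched random lists, for shRCOR1 (orange) and shRCOR2 (blue); filled points lie outside the central range of 10000 matched lists. Sterol biosynthesis lay below matched lists in shRCOR2 (-0.81 against -0.26 log2) and above them in shRCOR1 (0.12 against -0.05 log2).

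The named genes that fell in shRCOR1 were also single genes of varied function. RTN3, a reticulon of the tubular endoplasmic reticulum (chromosome 11, 63681446 to 63759891), fell from 187 TPM to 24.7 and 14.2 (limma log2 over shCTRL -3.47, SE 0.32, adjusted p = 0.0097), and so did its processed pseudogene RTN3P1, which is uncertain because it shares reads. MARCKS, an actin-linked substrate of protein kinase C, fell from 197 TPM to 43.7 and 31.5 (limma log2 -2.38, SE 0.25, adjusted p = 0.013), and NDUFA5, a subunit of complex I, fell from 84.5 TPM to 12.6 and 12. LIN28B, which blocks maturation of let-7 microRNAs and is highly expressed in neuroblastoma, fell from 81.9 TPM to 19.0 and 12.6 (limma log2 -2.16, SE 0.24, adjusted p = 0.018). EIF4EBP2, a repressor of cap-dependent translation, fell from 53.6 TPM to 13.3 and 9.14, and UFM1, a ubiquitin-like modifier, from 33.1 TPM to 8.02 and 6.63. NUP43, PREPL and ALKBH8 also fell, while SENP3-EIF4A1 (limma adjusted p = 0.12) and the pseudogene CHCHD3P3 (adjusted p = 0.051) did not pass.

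Among the 12 genes named as higher in shRCOR1, limma passed 3, H2BP2 and DERPC among them, with adjusted p between 0.0045 and 0.025. H2BP2 rose from 2.98 TPM to 26.5 and 22.9, while it stood at 34.3 TPM in untreated shCTRL and 35.9 TPM in untreated shRCOR2. DERPC rose from 2.58 TPM to 11.9 and 9.07, with shCTRL at 31.4, 4.47 and 4.79 TPM. HMOX1, the heme oxygenase induced by oxidative stress, measured 19.7, 60.6 and 91.0 TPM (limma adjusted p = 0.32), and SLC40A1, the iron exporter ferroportin, 4.88, 10.9 and 18.4 TPM (limma adjusted p = 0.20). NUAK1, GTF2H5, C3orf14, RNU11, EIF3F, ZNHIT3 and FAM3C2P also did not pass. The 3′ UTRs of 8 of the 9 lower genes that could be searched held the 6-base word GTGATA, against 27.1% of the 9803 genes. That word came from a scan of these same shRCOR1 changes, so the share is no independent support. Random sets matched on 3′ UTR length and GC to the genes lower by the size rule held it at 40.8% on average.

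By the size rule 42 genes were higher and 139 lower in shRCOR1, and 81.3% of the lower genes were protein-coding. Over shCTRL, limma called 38 genes, 12 higher and 26 lower, of 1206 at an unadjusted p under 0.05. Under median-of-ratios scaling limma called 0 genes with 1319 at an unadjusted p under 0.05, the 10 named genes that fell having adjusted p between 0.05 and 0.11 with changes of similar size, -3.41 log2 for RTN3 and -2.32 for MARCKS. With untreated shCTRL replaced by the mean of the other untreated libraries, limma called 161 genes, 31 of them shared. Part of the untreated shRCOR1 level cancels in that fit and differences between the untreated lines enter, so the larger count is no support for the calls. Fits without 1 doxycycline library of shRCOR1 or shCTRL called more genes than the main fit. With 1 residual degree of freedom each, their larger counts are no support for the calls.

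In the p53 target list 4 genes passed as lower when adjusted over the list alone, namely MDM2, the ubiquitin ligase that restrains p53, at 48.1, 26.7 and 17.7 TPM, the death receptor TNFRSF10B at 22.9, 8.51 and 8.31 TPM, PMAIP1 and ZMAT3, although the list median of -0.05 log2 lay at percentile 41.21. Integrated stress response genes had a median of -0.44 log2 over shCTRL (percentile 0) with PSAT1, at 73.2, 42.3 and 36.5 TPM, as the 1 gene passing adjusted over the list alone, but 0.07 log2 against the own untreated library (percentile 93.63), since shCTRL stood at 0.61. Immediate early genes had a median of -0.27 log2 (percentile 2.03, 22.98 at 48 h alone and up to 32.56 under other settings), and sterol biosynthesis genes a median of 0.12 log2 (percentile 99.40, from 34.8 at 24 h and 100 at 48 h) and 0.45 log2 against the own untreated library, with 0 genes passing limma adjusted over either list alone. In the sterol list INSIG1 measured 56.2, 64.8 and 111 TPM while IDI1, at 55.8, 36.2 and 27.3 TPM, was among the 3 with an unadjusted p under 0.05, which were lower. Of the ER chaperones DNAJB11, at 71.0, 37.4 and 29.3 TPM, and CANX, at 438, 288 and 264 TPM, passed as lower adjusted over the list alone, 2 genes in a list at percentile 74.31.

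For the next lists in shRCOR1 limma passed 0 genes, over all genes and adjusted over the list alone. Adrenergic transcription factors had a median of -0.04 log2 (percentile 68.08, 1 gene at an unadjusted p under 0.05), with PHOX2A, a regulator of noradrenergic identity, at 181, 111 and 73.1 TPM. The noradrenergic phenotype list stood at -0.06 log2 (percentile 43.49, 3 unadjusted), mesenchymal markers at 0.08 (percentile 92.77, 0 unadjusted), CoREST members at 0.00 (percentile 71.53, 1 unadjusted) and REST-bound neuronal genes at -0.01 (percentile 67.37, 1 higher and 3 lower unadjusted). Neurite and cytoskeleton genes stood at 0.05 log2 (percentile 93.81, 1 higher and 1 lower unadjusted) and at percentile 100 against the own untreated library, with SEMA3A, a guidance cue, at 8.93, 15.1 and 31.0 TPM. DNA replication stood at -0.15 log2 (percentile 8.93, 1 unadjusted), mitosis at 0.00 (percentile 85.29, 0 unadjusted), ribosome biogenesis at -0.20 (percentile 2.85, down to 0.52 under other settings, 0 unadjusted) and glycolysis and hypoxia at -0.19 (percentile 5.46, 1 unadjusted). Against the own untreated library, without shCTRL subtracted, several lists within the range over shCTRL lay outside it, among them glycolysis at percentile 0.36, DNA replication at 0.05, the Notch pathway at 0.38, mesenchymal markers at 99.02 and ER chaperones at 98.28. Apoptosis regulators stood at -0.13 log2 (percentile 15.20, 4 unadjusted), the Notch pathway at -0.09 (percentile 33.00, 0 unadjusted) and the interferon response at 0.01 (percentile 58.70, 1 unadjusted). Schwann and glial markers stood at -0.24 log2 (percentile 16.26, 0 unadjusted) but at 0.69 log2 against the own untreated library (percentile 99.95), where shCTRL stood at 0.79, fibroblast, endothelial and blood markers at 0.27 (percentile 97.83, 95.77 at 48 h alone and down to 96.3 under other settings, 1 unadjusted), with COL3A1 at 16.5, 14.7 and 64.8 TPM, histones at 0.07 (percentile 99.04, 94.36 at 48 h alone and down to 57.67 under other settings, 0 unadjusted) and small RNA and nuclear transcripts at 0.16 (percentile 99.89, down to 69.35 under other settings, 1 unadjusted). Mitochondrially encoded mRNAs stood at -0.58 log2 over shCTRL (percentile 0) and 0.67 log2 above the own untreated library. None passed over all genes and 6 had an unadjusted p under 0.05. MT-ND3, MT-ND4L and MT-ND6, 3 genes, passed adjusted over the list alone with a smaller doxycycline change than in shCTRL.

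The knockdowns were then compared with each other. Limma called 36 genes for shRCOR2 over shRCOR1, 18 higher and 18 lower, of 2216 at an unadjusted p under 0.05; ACTB, TXNRD1, SRXN1 and DNMT3B were lower in shRCOR2 and RTN3, MARCKS, LIN28B and NDUFA5 lower in shRCOR1. Against matched lists, the change in shRCOR2 minus that in shRCOR1 lay at percentile 0 for sterol biosynthesis, 0.09 for glycolysis and hypoxia and 0.03 for both mitosis and mesenchymal markers. It lay at percentile 100 for immediate early genes, the integrated stress response and p53 targets, at 99.46 for the noradrenergic phenotype list and at 99.77 for small RNA and nuclear transcripts. ER chaperones lay at percentile 2.21, neurite genes at 1.05 and fibroblast, endothelial and blood markers at 2.34. Under median-of-ratios scaling limma called 0 genes with 2224 at an unadjusted p under 0.05. Fits without 1 doxycycline library of either targeted line called more genes than the main fit. With 1 residual degree of freedom each, their larger counts are no support for the calls.

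By the size rule, 9 genes were lower in both targeted lines, where independent lists would share 1.77. Named genes among them were ADORA2A, an adenosine receptor, DPY19L1, the peroxisome biogenesis factor PEX19, the glycolytic regulator PFKFB3, the DNA glycosylase TDG, UBE2Q2 and the readthrough gene TGIF2-RAB5IF. The 2 genes higher in both were BRD9P2 and SPECC1L-ADORA2A, where 0.07 would be shared by independent lists. ADORA2A was also lower and SPECC1L-ADORA2A, a readthrough gene containing it, higher in shCTRL, so their values are uncertain as overlapping genes. ACTA2, ADM2, CHAC1 and INHBE, with SPECC1L-ADORA2A, were the 5 genes higher in both shRCOR2 and shCTRL, where 0.09 would be shared. Lower genes shared with shCTRL were 2 for shRCOR1, where 0.28 would be shared, and 2 for shRCOR2, where 0.38 would be. An excess over independent lists was thus not particular to the targeted lines. Across 14997 genes, which are not independent replicates, the changes of shRCOR1 and shRCOR2 against their own untreated libraries had a Pearson r of 0.131 and a Spearman rho of 0.133. The same values were 0.135 and 0.167 for shRCOR1 with shCTRL and 0.036 and -0.003 for shRCOR2 with shCTRL.

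The untreated lines differed before induction. TH and DBH, which encode enzymes of noradrenaline synthesis, measured 38.2 and 215 TPM in untreated shCTRL, 90.1 and 402 TPM in untreated shRCOR1 and 111 and 375 TPM in untreated shRCOR2. PRRX1, a mesenchymal transcription factor, measured 5.17 TPM in untreated shCTRL, 0.963 in untreated shRCOR1 and 1.84 in untreated shRCOR2. At least 2-fold differences from untreated shCTRL were seen for 208 genes in untreated shRCOR1, 115 higher and 93 lower, and for 166 genes in untreated shRCOR2, 100 higher and 66 lower, a split that scaling changed to 82 and 85. Untreated shRCOR2 differed from untreated shRCOR1 in 163 genes, 95 higher and 68 lower. These counts compare pairs of libraries and carry no test.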

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

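The limma contrast and its scaling were planned, the test on list members without the core word was written down before its result, and the other tests below were chosen only after the results were seen. The targeted lines differed in which genes were lower: limma called 36 genes for shRCOR2 over shRCOR1, and 20 of the named genes were among them, with adjusted p between 0.02 and 0.041; under median-of-ratios scaling none of the 20 passed. Lower in shRCOR2, in log2 units of shRCOR2 minus shRCOR1, were the redox genes TXNRD1 at -2.39 and SRXN1 at -2.24, the actin gene ACTB at -2.19 and the DNA methyltransferase DNMT3B at -2.56. C4orf3 stood at -2.44, CNOT11 at -1.88 and SMN2, which shares reads with SMN1, at -1.80. Lower in shRCOR1 were the reticulon RTN3 at 3.09 with its pseudogene RTN3P1 at 2.52, the protein kinase C substrate MARCKS at 2.03, the complex I subunit NDUFA5 at 2.22 and the let-7 inhibitor LIN28B at 2.2. NUP43 at 2.40, PREPL at 2.23, EIF4EBP2 at 2.18, UFM1 at 1.77 and the pseudogene CHCHD3P3 at 2.27 went the same way. H2BP2 at -3.36 and DERPC at -2.52 were higher in shRCOR1, where H2BP2 had been low in the untreated library.

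Each targeted line had more lower than higher genes, and their 3′ UTRs were rich in a short word: AGTGATA came first in shRCOR1 (z -20.31) and ATGGCTA in shRCOR2 (z -11.86), each present once in the transcript targeted in its line and absent from the other. In shCTRL the first word was AAGAGCA (z -7.14). It too was present once in the RCOR1 transcript and absent from that of RCOR2, so such a site does not mark the target. Pairing of the induced shRNA with 3′ UTRs, in the manner of a microRNA seed, may account for many of these genes, such as RTN3 and TXNRD1, which hold the 7-base word of their line, whereas ACTB holds only its 6-base core, as 35.3% of all searched genes do: the word found in a random part of the genes had a z of -13.61 in the others in shRCOR1, where it ranked 2 from the lowest, and of -9.08 in shRCOR2, where it ranked 1, below the -4.45 of shuffled changes. Those shuffles were of shCTRL changes over all 9803 genes, so that bound is not a like background for a part of the genes. Unshuffled shCTRL passed it too, at -7.14 over all genes, as did the next word in shRCOR2, at -7.34 in the other genes. The shCTRL line carries an shRNA as well, so it is no background free of such pairing. Whether its first word reflects pairing was not tested. Long 3′ UTRs alone were argued against, since among the genes not used to find the word 58.3% of the lower genes held it in shRCOR1 and 31.6% in shRCOR2, against at most 41.7% and 26.3% in random sets matched on length and GC. Loss of RCoR1 or RCoR2 stayed open as a cause for the rest, with 20 lower genes lacking the core in shRCOR1 and 26 in shRCOR2. These genes were not searched for other sites, so pairing stayed open for them as well. The shRNA sequences were not used here, and a second shRNA or a rescue would separate these explanations.

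Sterol, glycolysis and mitosis genes were low in shRCOR2. Pairing of the shRNA with the core in their 3′ UTRs was argued against as the sole cause. Over members without the core the highest of the 3 percentiles was 0.01. The medians of these members over shCTRL were -0.81, -0.60 and -0.57 log2 in that order, against -0.81, -0.77 and -0.61 for the whole lists. Members without the core were not searched for other sites. TGGCTAT, which lacks the core, was among the lowest words in shRCOR2 at 24 h (z -8.56), so pairing at other sites stayed open. The growing share of 7SL and other small RNAs did not account for the whole pattern. With TPM rescaled without these RNAs the highest of the 3 medians over shCTRL was -0.40 log2. An earlier form of this test by percentile was dropped because rescaling a library hardly moves a percentile. Loss of RCoR2, pairing at other sites or indirect effects of genes such as ACTB may each lie behind the pattern. So may a difference in growth or medium between the cultures. A design of 1 library per group cannot separate them.

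Mitochondrially encoded mRNAs had a smaller change after doxycycline in both targeted lines than in shCTRL. Untreated shCTRL standing apart from the other untreated libraries may explain the pattern: with the mean of the other untreated libraries in its place the lower of the medians was 0.19 log2. A first criterion, a gap of more than 1 log2 unit between untreated shCTRL and the other untreated libraries, was missed at 0.83, and the replacement test was adopted after that, when its outcome had already been estimated. Knockdown lowering these mRNAs stayed open: they were higher after doxycycline in each line by itself, the smaller median in the targeted lines being 0.48 log2 against 1.41 in shCTRL, but a lowering on top of a doxycycline effect would leave such values too. Doxycycline, which inhibits mitochondrial translation, also stayed open as a cause of the higher values. The untreated libraries are listed at 48 h, so at 24 h time and doxycycline cannot be told apart. In shRCOR2 the median of these mRNAs was 1040 TPM untreated, 1930 TPM at 24 h and 1160 TPM at 48 h.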

How the results depend on the processing

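No paired analysis was possible because the labels give no replicate numbers; libraries were matched only by line and time, each line with its own untreated library. Results were recomputed under other settings, of which the rescaling without small structured RNAs, the replacement of untreated shCTRL, the shCTRL change not subtracted and all settings of the untreated lines were chosen after seeing the data. The cause was not tested where a count moved.

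The size rule gave 82 genes in shCTRL, 181 in shRCOR1 and 216 in shRCOR2. A 1.5-fold threshold gave 279, 826 and 974 genes, 24 h alone 227, 389 and 366, and 48 h alone 170, 597 and 984. A pseudocount of 0.1 TPM gave 163, 338 and 359 genes, one of 5 TPM 38, 82 and 94, and a mean of at least 5 TPM gave 50 in shCTRL. With the shCTRL change subtracted there were 323 genes in shRCOR1 and 366 in shRCOR2. Median-of-ratios scaling kept the counts within 1.5 times, at 77, 172 and 168.

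Limma called 33 genes for shRCOR2 over shCTRL, 38 for shRCOR1 over shCTRL, 36 for shRCOR2 over shRCOR1 and 41 for shCTRL doxycycline. In that order, median-of-ratios scaling gave 2, 0, 0 and 23 genes, with 1805, 1319, 2224 and 1093 at an unadjusted p under 0.05, and rescaling without small structured RNAs gave 6, 23, 19 and 25. No filter gave 0, 168, 160 and 117 genes, the 0 standing beside 4062 at an unadjusted limma p under 0.05, and leaving out the time term gave 8, 24, 15 and 12. A mean of at least 5 TPM gave 66, 65 and 69 genes for the first 3 contrasts, and comparing doxycycline libraries directly gave 892, 669 and 2167. The direct comparison leaves out the untreated libraries, so its counts also hold differences between the lines before induction. Robust moderation gave 66 genes for shRCOR1 over shCTRL and 67 between the targeted lines, and a pseudocount of 0.1 TPM gave 17 for shRCOR2 over shCTRL. With untreated shCTRL replaced there were 328 genes for shRCOR2, 161 for shRCOR1 and 15 for shCTRL, and with the shCTRL change not subtracted 116 and 100. Replacing untreated shCTRL lets part of each targeted line's untreated level cancel, so the larger counts are no support for the calls. Leaving out 1 doxycycline library gave 45 to 794 genes for shRCOR2 over shCTRL, 158 to 640 for shRCOR1 over shCTRL, 39 to 1825 between the targeted lines and 136 to 139 for shCTRL.

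The untreated lines differed in 208 genes for shRCOR1 and 166 for shRCOR2 against shCTRL and in 163 between the targeted lines. A pseudocount of 0.1 TPM gave 437, 383 and 357 genes, one of 5 TPM 73, 56 and 47, and a mean of at least 5 TPM 96, 76 and 59. Over 318 settings of 46 list results, 281 stayed the same, 17 were weaker, 15 stronger and 5 reversed. The reversed values, list medians minus those of matched lists, arose with the shCTRL change not subtracted, at 0.106 log2 for the integrated stress response in shRCOR1 and at 0.796 and 0.703 log2 for mitochondrially encoded mRNAs in shRCOR1 and shRCOR2, whose own changes were above 0. Schwann and glial markers, within the range of matched lists over shCTRL, stood at 0.669 and 0.481 log2 in the same comparison. Of 144 settings of 48 named genes, 132 stayed the same and 12 moved. Knockdown stayed at -0.942 to -0.776 log2 for RCOR1 and -2.353 to -2.103 log2 for RCOR2 from TPM, and stood at -1.115 and -2.177 log2 from coverage.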

Other observations

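Both tests below were chosen only after the lower genes were seen. In shRCOR2, where ACTB fell, some other actin and adhesion genes measured higher than untreated, though CNN2, the one furthest above shCTRL, did not pass limma (adjusted p = 0.244). ACTG1, the other cytoplasmic actin, measured 1910, 2490 and 2280 TPM, the calponin CNN2 30.8, 73.4 and 59.3 TPM and the focal adhesion gene VCL 35.3, 57.5 and 44.6 TPM. ACTA2, smooth muscle actin, measured 1.78, 5.29 and 9.16 TPM, and SRF itself 21.3, 20.7 and 18.6 TPM. The tropomyosin gene TPM1, at 247, 231 and 132 TPM, and CNN1, at 5.67, 3.81 and 1.76 TPM, went the other way, and over shCTRL so did FHL1 at -0.13, CALD1 at -0.19 and SRF at -0.21 log2.

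These genes and several immediate early genes are targets of SRF, whose cofactor MRTF is held in the cytoplasm by free actin, so that loss of actin monomer could release it. SRF targets other than ACTB and the immediate early genes had a median of 0.28 log2 over shCTRL in shRCOR2 against -0.21 in matched lists (percentile 99.98), and 0.26 log2 without ACTA2, which had been seen before. In shRCOR1, where ACTB measured 3640, 3570 and 3370 TPM, they lay at percentile 3.97. Higher SRF activity after loss of ACTB is therefore a possible explanation of the higher median of these targets. That change would then follow from a gene whose 3′ UTR holds the 6-base core, though not the whole word, found in shRCOR2. Whether it extends to EGR1 and FOS was not tested, since the list left out the immediate early genes. Other routes to higher immediate early genes were not examined. Protein levels, actin polymerisation and MRTF location were not analysed here.

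The fall of TXNRD1 and SRXN1 raised the possibility of lower NRF2 activity, since both are NRF2 targets. The other NRF2 targets had a median of -0.44 log2 over shCTRL in shRCOR2 against -0.23 in matched lists, at percentile 3.12, which missed the bound of 2.5 set for the test, and lay at percentile 55.9 against the own untreated library. A looser bound tried after this value was seen was dropped. Without HMOX1 and SLC7A11, which had been seen before, the percentile was 4.33. Lower NRF2 activity was thus not borne out, although the value lay close to the bound; TXNRD1 and SRXN1 both hold the 6-base core in their 3′ UTRs.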
